A study of Mus musculus with 2 samples.

How the data were processed

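The acetylation of lysine 27 on histone H3 (H3K27ac), a mark of active promoters and enhancers, was profiled by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in mouse limb tissue at embryonic day 12.5. Per the labels, the samples were 2 biological replicates of a single group, made from strain B6NCrl embryos of both sexes. Replicate 1 was a pool of 88 embryos and replicate 2 a pool of 68 embryos, and the labels do not separate forelimb from hindlimb. With 1 group there was no contrast between conditions, so the comparisons were between replicates, between gene lists, and between regions of the genome.

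The deposited data were 4 peak lists on the mm10 build: a list for each replicate, a list called on both replicates pooled, and a list of replicated peaks. Per the texts deposited beside the lists, each list was derived from filtered alignments and control files, and the replicated list was derived from the pooled list and both replicate lists. The aligner, the peak caller, its threshold and the rule for the replicated list are not given in the sources used here. The signal value of each peak is a deposited value on the scale of the authors' caller, which was not stated. It served to describe, rank or filter peaks within a list. Signal was also compared between the replicate lists, which assumes that both are on a common scale. The deposited −log10 p and −log10 q of each peak, as the authors' caller gave them, were used to describe the lists. The deposited position of each summit was used to place windows around summits. The lists give no read counts, so the depth of each library is unknown and no interval that needs it was computed.

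Annotation came from GENCODE vM21 basic genes, and sequence with repeat masking from the GRCm38.p6 reference, which has the same chromosome sequences as mm10. Every deposited peak ended within its chromosome. The 10 peaks of each replicate list, 9 of the pooled list and 8 of the replicated list that lay on sequences other than the main chromosomes were left out. All coordinates are 1-based on mm10. Computations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.

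The replicated list was the main set. Peaks of different lists were called shared when they overlapped by at least 0.5 of either peak, and the share was set against 100 circular shifts of the other list within each chromosome. Correlations of signal were computed across pairs of most overlapping peaks; peaks are not independent replicates, and no p-value was attached. A promoter peak lay within 1 kb of an annotated transcription start site (TSS) of a protein-coding gene, and all other peaks were called distal. Promoters were divided into 10 equal classes by their ratio of observed to expected CpG in 1 kb.

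Before the data were examined, 23 gene lists were fixed. They held limb patterning, ectoderm and apical ridge, chondrogenic, late osteoblast, tendon and joint, muscle, endothelium, erythroid, macrophage, Schwann and neural crest, neural, heart, liver, pluripotency, housekeeping, hedgehog, FGF feedback, Wnt and retinoic acid genes, and the HoxA, HoxB, HoxC and HoxD clusters. The symbols Ahsp and Emr1 had no match in the annotation and were left out. For each list, the share of members with a promoter peak was given a percentile among 10000 random lists of the same size matched on CpG class. The median number of distal peaks in the domains of its members was likewise ranked among 10000 random lists matched on domain length in 10 classes. A domain ran from 5 kb upstream to 1 kb downstream of the TSS and was extended to the neighbouring basal domains by at most 1 Mb. Percentiles describe these libraries and are not p-values, because genes are not replicates.

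Peaks were also counted in 19 intervals fixed in advance. Distal peaks within 12.5 kb of each other were stitched into clusters, which were ranked by the base pairs that peaks covered. For 17 short consensus sequences, matches per kb on both strands of distal peaks were divided by matches per kb in peak-free flanks of equal length 5 kb away. The ratio was ranked among up to 200 consensuses with the same letters in another order.

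The rule for the genes named in the text was also fixed in advance. It took every Hox gene, the genes that bound the intervals, and the nearest genes of the 15 largest clusters. From each list it took up to 4 members with the most distal peaks and up to 4 members with no promoter peak. From the lists of other cell types it also took up to 4 members with the strongest promoter peaks. Tbx2, Tbx4, Tbx5, Grem1 and Lmbr1 are outside this rule and are named because they lie in the intervals. Cdk2, Sdhc and Sympk, which share a promoter peak with a named gene, and the genes beside the clusters and at the widest and strongest peaks are also outside it and were picked after their values were seen.

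The scripts were tested on simulated data. In a set of 63766 simulated peaks, 100% of the planted shared peaks were found, and 1.18% of shifted peaks overlapped by chance. Among unchanged simulated lists drawn from 21827 genes, 4.2% reached the 95th percentile, or 5.7% when drawn from CpG-rich genes. In a further run, about 40 percent of the members, picked at random, were made occupied in addition to those already occupied. Then 89% of lists reached it. A motif planted at a ratio of 2.62 in 5000 simulated peaks was found at 2.62, while the highest of its 119 permuted forms reached 1.37.

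The alternatives tried were an overlap of at least 1 bp or of at least 0.5 of both peaks, only the peaks above the median signal of each list, each replicate list alone, and the pooled list. Further alternatives were a promoter window of 2.5 kb, the TSS of all annotated genes, no matching of random lists, domains of at most 100 kb, stitching within 5 kb, clusters ranked by signal times width, windows of 200 bp around summits, flanks 20 kb away, and signal pairs that were each other's single partner. The replicated peaks found in both replicate lists and motif counts without repeat-masked bases were added after seeing the data. The ranks of the intervals among 10000 random windows of the same length, with at most 10 percent of gap, were also added after seeing the data.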

Results

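H3K27ac was mapped in limb buds at embryonic day 12.5, when the digits are being laid down and cartilage condensations form, in 2 pools of embryos. The list of replicate 1 held 103366 peaks covering 47.0 Mb and that of replicate 2 held 119382 peaks covering 55.6 Mb. The pooled list held 126122 peaks (67.9 Mb) and the replicated list 63774 peaks (52.4 Mb, or 1.92% of the main chromosomes). The median peak was 557 bp wide in the replicated list and 275 and 278 bp in the lists of replicates 1 and 2. Read depth is unknown, since the lists give no counts. Signal values are the authors' own peak scores and are given for the replicated list unless a replicate is named.

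The first comparison asked at which promoters the limb carried H3K27ac. Of the 42 limb patterning genes, 41 (97.6%) held a replicated promoter peak, against a median of 73.8% among random lists of the same CpG content (percentile 100). They included Wnt5a, which encodes a secreted ligand for limb outgrowth (ENSMUSG00000021994.15, chromosome 14, 28504750 to 28527448). Its signal was 44.1, with 33.0 in replicate 1 and 39.7 in replicate 2. Also marked was the zinc finger gene Gli3 (ENSMUSG00000021318.15, chromosome 13, 15463235 to 15730026; signal 46.2, with 37.5 and 39.6). The exception was Shh, the posterior signal of the limb bud (ENSMUSG00000002633.4, chromosome 5, 28456815 to 28467256), which had no promoter peak in the replicated list or in either replicate list. Chondrogenic genes held a peak at 19 of 25 promoters (76.0%, percentile 99.9), led by Sox9, the master regulator of cartilage (ENSMUSG00000000567.5, chromosome 11, 112782224 to 112787760), with a signal of 28.9 (22.8 and 28.3). The members without one included Col10a1, Cytl1, Ihh and Matn1. Ihh had weak peaks in both replicate lists (2.77 and 3.47) but none in the replicated list.

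Tendon and joint genes were marked at 12 of 14 promoters (85.7%, percentile 99.9), among them the TGF-beta receptor gene Tgfbr2 (22.9) and the joint gene Erg (10.2), but not the late tendon genes Tnmd and Thbs4. Late osteoblast genes were marked at 3 of 12 (percentile 28.7), with no peak at Bglap, Bglap2 or Alpl. Muscle genes were marked at 12 of 22 (54.5%, percentile 99.1; 93.7 in the list of replicate 1 alone, 47.6 among the peaks above the median signal and 59.4 without matching). The strongest of these were Six1 (15.2), Mymk (12.8) and Lbx1 (5.60), and Tnnt3 and Chrna1 were also marked. Members without a replicated promoter peak included Acta1, Actc1, Chrng, Myf6 and Pax3. Whether marking followed the stage of muscle differentiation was not tested. All 25 housekeeping promoters were marked (percentile 99.9), with Actb at 53.0.

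Ectoderm and apical ridge genes were marked at 8 of 23 promoters (34.8%), against a random median of 65.2% (percentile 0.065). Dlx5 (7.47), En1 (5.29), Fgf9 (4.39) and Dlx6 (4.02) were the strongest, and the epithelial genes Cdh1, Cldn6 and Esrp1 and the ridge gene Fgf17 had no replicated peak. How low the rank was depended on the list. The percentile was 6.97 with the pooled list, 0 in the list of replicate 1 alone and 21.8 in that of replicate 2 alone. In the list of replicate 2, Cdh1 (2.94) and Grhl3 (3.01) had weak peaks. Endothelial genes were marked at 6 of 18 (33.3%, percentile 4.77), but ranked at 39.5 and 33.5 in the lists of replicates 1 and 2 and at 69.1 in the pooled list. Fli1 (25.4), Erg (10.2, also in the tendon and joint list) and Egfl7 (5.60) were marked, and Cdh5, Cldn5, Emcn and Etv2 were not.

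Of 24 neural genes, 3 were marked (12.5%, percentile 0 against a random median of 66.7%), namely Emx2 (9.02), Isl1 (4.04) and Rbfox3 (2.80); Emx2 and Isl1 also act in the limb girdles and the early hindlimb. Liver genes were marked at 1 of 21 promoters (Foxa3, 5.60; percentile 0.315, or 5.03 in a window of 2.5 kb) and pluripotency genes at 1 of 12 (Esrrb, 3.58; percentile 0.015). Heart genes were marked at 3 of 17 (Hcn4 4.36, Myh7 4.04, Smyd1 2.49; percentile 4.24), with percentiles of 48.7 and 42.2 in the lists of replicates 1 and 2. Macrophage genes were marked at 2 of 14 (Cd68 4.04, Aif1 2.64; percentile 61.5, or 97.1 in a window of 2.5 kb and 0.195 without matching) and Schwann and neural crest genes at 5 of 12 (percentile 64.6), led by Pmel (21.9) and Mpz (8.87), whose peaks also reached the promoters of Cdk2 and Sdhc. Erythroid genes were marked at 6 of 18 (percentile 99.0), namely the regulators Klf1 (7.16), Nfe2 (4.92) and Tal1 (4.32), the receptor gene Epor (4.04) and the membrane genes Epb42 (3.27, named after its value was seen) and Gypa (2.96). No globin promoter carried a peak, while the domain of Hba-a2 held 1 distal peak (named after its value was seen). The erythroid rank was 6.07 without CpG matching and 89.1 among replicated peaks found in both replicate lists.

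The hedgehog, retinoic acid and Wnt lists differed less from random lists at promoters than in their surroundings. For FGF feedback this cannot be judged, since all its members were marked. Ties with random lists count only in part, so 93.3 was the highest percentile it could reach. FGF feedback genes were marked at 13 of 13 promoters (percentile 93.3), hedgehog genes at 11 of 13 (percentile 76.2; 98.6 in the list of replicate 1 alone), retinoic acid genes at 11 of 16 (percentile 54.9) and Wnt genes at 13 of 17 (percentile 37.4, or 97.8 without matching). Unmarked members included the hedgehog target Hhip, the Wnt targets Sp5 and Tcf7 and the Wnt antagonist Dkk1. Of these, Hhip (2.27) and Tcf7 (3.33) had weak peaks in the list of replicate 1. Among marked members of the hedgehog list, Ptch1 had a signal of 44.0 (named after its value was seen). Among retinoic acid genes, the synthesis genes Aldh1a2 and Aldh1a3 and the degradation genes Cyp26a1 and Cyp26c1 were unmarked, while Cyp26b1, the degradation enzyme of the distal limb, had a signal of 22.05.

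**Figure D1:**
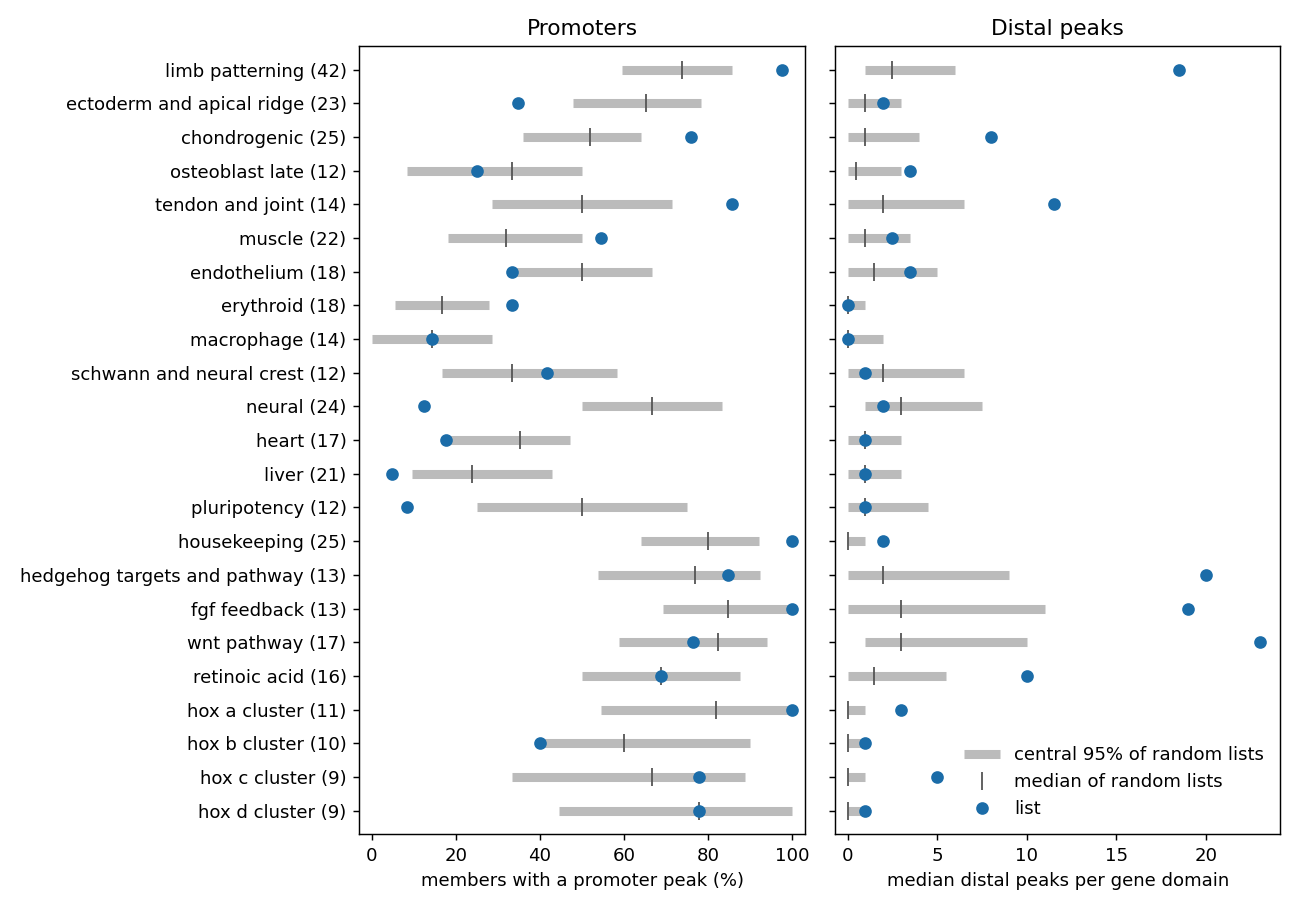
Members of each gene list with a replicated promoter peak (left, percent) and the median number of distal replicated peaks per gene domain (right). Dots are the lists with their number of members, grey bars the central 95 percent of 10000 matched random lists and ticks their medians; limb patterning lies above the bar in both panels and neural genes below it at promoters only.

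The second comparison counted distal peaks, where enhancers lie, in the domain of each gene. Limb patterning genes had a median of 18.5 distal replicated peaks against 2.5 in random lists of the same domain length (percentile 100). Wnt5a had 93 (138 and 158 in the lists of replicates 1 and 2), Lmx1b, which sets dorsal identity, 77 (139 and 144), the T-box gene Tbx3 70 and Gli3 56. Shh had 3 in a domain of 873 kb. Among chondrogenic genes (median 8, percentile 99.98), Sox9 had 129 (195 and 224), its partners Sox5 and Sox6 95 and 66, and Runx3 43. Among tendon and joint genes (median 11.5, percentile 99.97), Tgfbr2 had 108, Erg 36 and Osr1 31.

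The signalling lists all ranked high, but lists overlapped and are not independent. Cyp26b1 is in both the FGF feedback and retinoic acid lists. Wnt5a and Gli3 are in the limb patterning list and also in the Wnt and hedgehog lists, respectively. Wnt genes had a median of 23 (percentile 100), with 127 peaks around Tcf7l2 and 50 around Ctnnb1, and hedgehog genes 20 (percentile 99.97), with 115 around the co-receptor gene Gas1 (chromosome 13, 60174405 to 60177365), 71 around Boc and 50 around Gli2. FGF feedback genes had 19 (percentile 99.93), with 82 around Cyp26b1, and retinoic acid genes 10 (percentile 99.9), with 56 around Rxra. Housekeeping genes had 2 (percentile 99.3; 94.0 among replicated peaks found in both replicate lists), with 40 around Hprt and 27 around Ywhaz. Late osteoblast genes had 3.5 (percentile 98.5; 79.4 in the list of replicate 1 alone), with 9 each around Mepe, Sp7 and Spp1. All 4 Hox clusters ranked at 95.1 or above, HoxB at 95.1 with 1 peak (89.5 and 92.9 in the lists of replicates 1 and 2), HoxD at 97.2 with 1, HoxC at 99.995 with 5 and HoxA at 100 with 3. Neighbouring Hox genes share peaks, so their members do not count independently, and with the TSS of all genes HoxA, HoxB and HoxD ranked at 49.985, 49.3 and 49.985. HoxD also ranked at 48.8 among replicated peaks found in both replicate lists. A rank just below 50 is what a list tied with nearly all random lists receives. Such ranks show a loss of the difference, not a reversed direction.

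Lists of other cell types lay nearer the random medians. Ectoderm and apical ridge genes had a median of 2 (percentile 83.8), with 18 peaks around Fgf9, 16 around Grhl3, 14 around Trp63, the master gene of stratified epithelium, and 12 around Epcam. Muscle genes had 2.5 (percentile 89.1; 96.2 in the list of replicate 1 alone), with 23 around Tnnt3 and 19 around Cdh15. Endothelial genes had 3.5 (percentile 91.0; 96.2 in the list of replicate 1 alone), with 45 around Cdh5, 38 around Fli1 and 36 around Erg. Percentiles were 63.6 for heart (median 1), 58.6 for liver (1), 44.0 for pluripotency (1), 41.1 for erythroid (0), 29.3 for macrophage (0), 28.7 for Schwann and neural crest (1) and 22.5 for neural genes (2). Single members stood out, with 53 peaks in the domain of the leukocyte gene Ptprc, 45 in that of Tfcp2l1 and 25 in that of Apoa1. Peaks were assigned by position alone, so a peak in a domain need not act on its gene.

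The third comparison covered the Hox clusters, which pattern the limb along its axis. In HoxD, the strongest promoter peaks were at Hoxd12 (signal 29.1), Hoxd11 (26.1), Hoxd9 (20.5), Hoxd13 (17.9), Hoxd10 (17.7) and Hoxd8 (13.2), followed by Hoxd3 (6.73), and Hoxd1 and Hoxd4 had none. The Hoxd3 peak (74711826 to 74712542) also covered the annotated start of the Hoxd4 gene (74711929). The first protein-coding TSS of Hoxd4, which was the one used, lies at 74721978. In HoxA, Hoxa10 and Hoxa11 shared a peak of 16067 bp (39.2), next to Hoxa9 (35.3), Hoxa7 (28.9) and Hoxa13 (25.2). Hoxa1 (4.92), Hoxa2 (4.02), Hoxa4 (3.84), Hoxa5 (5.13) and Hoxa6 (5.12) were weaker, and Hoxa3 (24.0) has an annotated transcript that starts beside Hoxa7. The HoxC genes were marked more weakly, from Hoxc11 (10.1), Hoxc10 (8.70), Hoxc5 (7.78) and Hoxc9 (5.76) to Hoxc6 (4.20), Hoxc4 (3.89) and Hoxc13 (3.11). The annotated start of the Hoxc5 gene lies near Hoxc10 (102967443) but was not used. Its first protein-coding TSS lies at 103013815. Hoxc12 had no promoter peak, and Hoxc8 had none in the replicated list but weak peaks in both replicate lists (3.32 and 2.94).

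In HoxB, 4 of 10 promoters were marked, Hoxb2 (6.26), Hoxb4 (5.44), Hoxb7 (3.73) and Hoxb3 (3.42), while Hoxb1, Hoxb5, Hoxb6, Hoxb8, Hoxb9 and Hoxb13 had no replicated promoter peak. Replicated peaks covered 58.9% of the HoxA cluster, 34.3% of HoxD, 31.0% of HoxC and 5.06% of HoxB. Among random windows these stood at percentiles 99.99, 99.86, 99.8 and 87.6. As lists of promoters matched on CpG, HoxC (7 of 9, percentile 83.3) and HoxD (7 of 9, percentile 49.8) differed less. HoxB ranked at 6.43 (4.36 and 37.8 in the lists of replicates 1 and 2). HoxA (11 of 11) ranked at 96.0, and at 94.7 and 93.8 in the lists of replicates 1 and 2. All 11 were marked in those lists too, so each value is the highest that HoxA could reach.

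**Figure D2:**
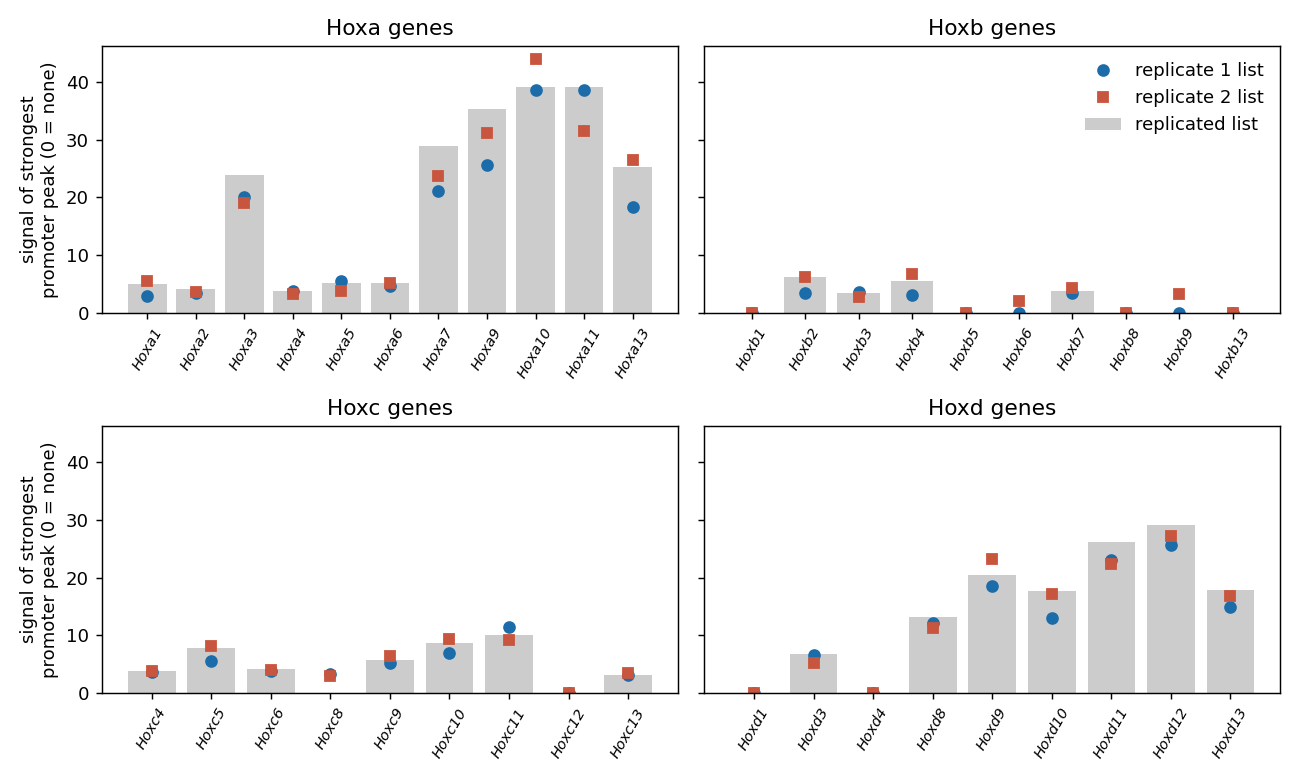
Signal of the strongest promoter peak of each Hox gene, in order of gene number within each cluster. Bars are the replicated list and points the lists of replicates 1 and 2, with 0 for no peak; HoxA reaches 39.2 and HoxD 29.1, while HoxB stays at or below 6.26 in the replicated list.

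The fourth comparison took intervals around limb genes. The gene desert on the Evx2 side of HoxD, known to hold digit enhancers (chromosome 2, 73911327 to 74652990), had 84 replicated peaks covering 8.46% (6.79% and 7.50% in replicates 1 and 2). The desert on the Hoxd1 side, known to hold forearm enhancers (74765143 to 75659260), had 41 peaks covering 2.99% (2.66% and 3.18%). The covered share was 2.83 times as large on the digit side, and the gap exceeded the difference between replicates on either side. Against random windows, the digit side ranked at 96.3 (94.1 in the list of replicate 2 alone) and the forearm side at 75.0. The interval from Hoxa13 to Jazf1, with Hoxa13 included, had 104 peaks covering 11.5% (percentile 98.7).

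**Figure D3:**
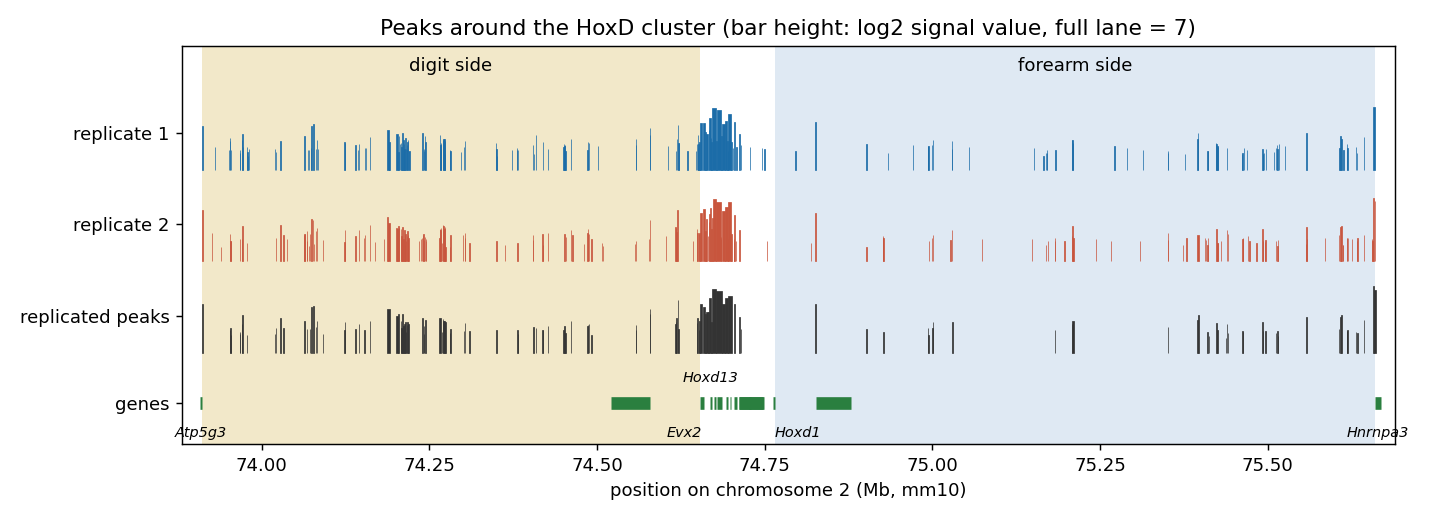
Peaks around the HoxD cluster on chromosome 2 in the lists of replicates 1 and 2 and in the replicated list, with bar height as log2 signal, and protein-coding genes below. Shading marks the desert on the digit side, where replicated peaks covered 8.46%, and on the forearm side, where they covered 2.99%.

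Some limb genes lay in densely marked intervals. The random windows were matched on length but not on gene content. The interval from Pitx1, the hindlimb selector, to Neurog1 had 53 peaks covering 16.5% (percentile 99.3), and that from Bcas3 to Brip1, which holds Tbx2 and the hindlimb gene Tbx4, had 97 peaks covering 10.2% (percentile 98.3). From Rbm19 to Med13l, which holds Tbx3 and the forelimb gene Tbx5, 104 peaks covered 5.53% (percentile 90.8). The interval of Fgf8 and Fbxw4 had 16 peaks covering 7.47% (percentile 92.5), of which 6 touched intron 1 of Fbxw4, the strongest at its promoter (signal 19.4), and 3 each touched introns 5 and 6. From Ihh to Pax3, 128 peaks covered 3.09% (percentile 75.0), and from Kcnj2 to Sox9, 83 peaks covered 3.02% (percentile 73.4).

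Other limb intervals were near or below the random median. The interval from Scg5 to Fmn1, which holds Grem1, had 8 peaks covering 1.13% (percentile 52.1), the desert between Meis2 and Spred1 had 11 covering 1.33% (percentile 51.3) and that between Bmp2 and Hao1 had 11 covering 0.790% (percentile 41.2). From Shh to Mnx1, 6 peaks covered 0.412% of 1022 kb (percentile 29.5), and of these 1 lay at the promoter of Lmbr1 (29378036 to 29379169, signal 4.82). The liver control from Alb to Afp and the Hbb globin cluster had 0 peaks in all 4 lists (percentiles 29.8 and 31.05). The median random window of these short lengths also had 0% covered, so the absence of peaks says little.

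The fifth comparison ranked stretches of distal acetylation. Stitching gave 18910 clusters, of which 9595 were single peaks and 480 had at least 10 kb covered. The largest, nearest to Pigc and with its middle in the body of Dnm3 (chromosome 1, 161962068 to 162257497), held 110 peaks covering 148 kb (136 and 144 kb in replicates 1 and 2). The second, around Cstad and beside the limb mesenchyme gene Prrx2 (chromosome 2, 30591181 to 30897495), held 83 peaks covering 114 kb. Here and below, a gene called beside a cluster lies in it or within 100 kb of it. Next came the clusters nearest to Lsp1, beside Igf2 (83.3 kb), Zfp36l1 (80.6 kb), Cpa5, beside Mest (80.2 kb), Haao (67.8 kb), Zmiz1 (66.5 kb), the Wnt5a receptor gene Ror2 (61.2 kb) and Fam92b (59.9 kb). The rest were nearest to Mvb12b, beside Lmx1b (55.4 kb), Sorl1 (55.0 kb), Igfbp4, beside Rara (54.0 kb), Fancc (53.6 kb), Mecom (52.8 kb) and Tcf7l1 (52.8 kb). Prrx2, Igf2, Mest and Dnm3 are outside the naming rule and were picked after the values were seen. In the list of replicate 2 alone, 9 of these 15 clusters were among its 15 largest.

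Over the whole genome, promoters carried 21.99% of replicated peaks (14019), against 2.95% after shifting, gene bodies 45.4% (38.9%) and intergenic sequence 32.6% (58.1%). Promoter peaks were wider than distal peaks (medians of 847 and 507 bp) and stronger (signal 7.01 and 3.72). Of 21827 protein-coding genes, 11335 (51.9%) had a promoter peak, from 2.34% in the lowest CpG class to 91.9% in the highest. The promoter share of peaks was 16.9% and 15.2% in the lists of replicates 1 and 2.

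Short sequence motifs were then compared between distal peaks and their flanks. The site of TEAD factors (GGAATGT) was 1.33 times as dense in peaks (percentile 100 of its permuted forms) and the forkhead site 1.07 times (percentile 100). The E-box CAGCTG, bound by myogenic and other bHLH factors, was 1.77 times as dense (percentile 97.6 of only 41 permuted forms, whose median ratio was 1.22). The posterior Hox site had a ratio of 0.817 and yet ranked at 96.5, since its permuted forms had a median of 0.689; the rank was 94.5 in the list of replicate 1 alone and 63.5 around summits. Matches of the CTCF site, an insulator motif, were fewer in peaks than in flanks (ratio 0.399, percentile 1.5). Without repeat-masked bases the direction turned, to a ratio of 1.32 (476 matches in peaks and 365 in flanks), and the percentile was 11.5.

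No other motif passed the 95th percentile or fell below the 5th. SRF ranked at 88.0 (99.5 with flanks 20 kb away), the homeodomain site TAATTA at 84.6, the E-box CAGATG at 81.5, AP-1 at 79.5, Gli at 71.5, Meis at 68.1 and the liver control HNF4 at 64.0. TAATTA had a ratio of 0.616 and only 13 permuted forms, so its rank is coarse. ETS ranked at 59.0, nuclear receptors at 45.4, Sox at 31.5, Pitx at 28.1 and GATA at 15.4. Ratios in the lists of replicates 1 and 2 were 1.27 and 1.26 for TEAD, 1.76 and 1.76 for CAGCTG, and 0.355 and 0.375 for CTCF with repeats included.

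The last comparison was between replicates. The strongest promoter peaks of the named genes were in both lists, as at Gas1 (49.9 and 57.7), Gli3 (37.5 and 39.6) and Sox9 (22.8 and 28.3). Weak promoters differed more, with Trp63 (4.54), Mitf (4.13) and Tek (3.20) found in replicate 2 and Gypa (4.16) in replicate 1 only. Over all peaks, 51.7% of replicate 1 peaks (53424) and 42.3% of replicate 2 peaks (50445) were shared, against 3.04% and 2.62% after shifting. By signal, the share was 27.8% and 19.7% in the lowest decile, 23.5% and 15.8% in the next and 99.9% and 99.8% in the highest. Peaks that were not shared (49932 and 68927) had medians of 218 and 223 bp, against 425 and 505 bp for shared peaks, and lay at promoters in 6.75% and 6.66% of cases against 26.4% and 26.9%.

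**Figure D4:**
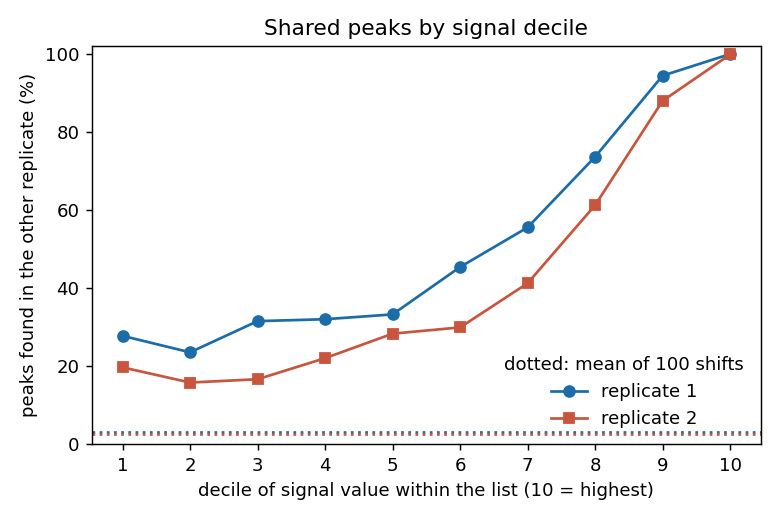
Peaks of each replicate found in the other replicate (percent) by decile of signal value within the list, from lowest to highest. Dotted lines are the means of 100 shifts, 3.04% and 2.62%; the share is 27.8% and 19.7% in the lowest decile and 99.9% and 99.8% in the highest.

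Across 51848 overlapping pairs of peaks, the Spearman correlation of signal was 0.697 and the Pearson correlation of log2 signal 0.86. The median log2 difference was 0.11 (replicate 2 minus replicate 1, SD 0.43 across pairs), and 97.4% of pairs were within 2-fold. Every replicated peak had the coordinates of a pooled peak. All 49752 pooled peaks found in both replicate lists were in the replicated list, where they made up 78.02%; it held 14014 further peaks. Of these, 4523 were in the list of replicate 1 only, 8889 in that of replicate 2 only and 602 in neither. They were narrower (340 against 678 bp) and less often at promoters (8.55% against 25.8%) than the rest of the replicated list.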

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

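The alternatives limited to replicated peaks found in both replicate lists and to bases outside repeats, and the tests of intervals against random windows, were chosen after the data were seen. No paired analysis was possible because the design has 1 group. Depth is unknown, so what it limits could not be measured. Of the motifs past a threshold, CTCF reversed its direction, from a ratio of 0.399 to 1.32 without repeat-masked bases, by the loss of matches within repeats. Among motifs past no threshold, 4 ratios crossed 1 under some alternative: AP-1 (0.966) and Meis (0.970) without repeat-masked bases, SRF without replicate 1 (0.932) and around summits (0.874), and nuclear receptors without replicate 2 (1.00064), in the pooled list (1.01) and around summits (1.04). Crossings of 50 were counted only for list percentiles that also passed the 5th or 95th percentile in either direction. At promoters there were 5. Without matching, these were erythroid (99.0 to 6.07), macrophage (61.5 to 0.195) and Wnt genes (37.4 to 97.8). The others were muscle above the median signal (99.1 to 47.6) and endothelium in the pooled list (4.77 to 69.1). For distal peaks, with the TSS of all genes HoxA and HoxD ranked at 49.985 and HoxB at 49.3. HoxD ranked at 49.8 above the median signal, 48.8 for peaks found in both lists and 49.5 with a 2.5 kb window. These distal ranks just below 50 are what ties with random lists give and show no reversed direction. No interval reversed. Leaving out a replicate left 6 gene lists at or above the 95th percentile at promoters and 12 to 13 for distal peaks, against 7 and 13 with the replicated list. Over the other alternatives these counts were 5 to 8 and 10 to 12, and limb patterning ranked above the 95th percentile in all of them. At promoters, 6 lists lay at or below the 5th percentile with the replicated list, against 3 without replicate 1, 5 without replicate 2, 3 with the pooled list and 2 with the 2.5 kb window. Of 374 further list percentiles computed under alternatives, 308 kept their side of the threshold, 37 lost it and 18 gained it in the same direction. The remaining 11 passed a threshold and also crossed 50, as given above. Of 95 interval percentiles, 94 kept their side of the threshold.

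With an overlap of 0.5 of both peaks, 33.2% of replicate 1 and 28.8% of replicate 2 peaks were shared, and 31143 pooled peaks were found in both lists. Among peaks above the median signal, these values were 58.6%, 53.3% and 30461. The Spearman correlation was 0.785 above the median signal and 0.644 for single partners. With an overlap of 1 bp, 6.004% and 6.15% of the peaks not shared by replicates 1 and 2 were at promoters.

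The promoter share of peaks was 34.2% above the median signal, 15.2 to 16.9% without a replicate, 14.2% in the pooled list, 25.8% for peaks found in both lists, 25.6% with a 2.5 kb window and 26.0% with the TSS of all genes. In the same order, the share of genes with a promoter peak was 46.6%, 54.1 to 55.3%, 56.8%, 49.9%, 53.6% and 28.04%. The last includes noncoding genes by construction. The ratio of the digit-side to the forearm-side desert of HoxD was 3.47 above the median signal, 2.36 to 2.55 without a replicate and 2.37 in the pooled list. Of the 15 largest clusters, 7 were kept above the median signal, 9 to 10 without a replicate, 9 in the pooled list, 7 with stitching within 5 kb and 9 when ranked by signal times width. Apart from the noncoding genes, the cause was not tested.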

Other observations

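The tests of CTCF sites outside repeats, of globin promoters, of ectoderm promoter signal, of neighbouring promoters and of ectoderm distal signal were chosen after the pattern they address was seen; for globins and ectoderm promoter signal the prediction was also written after the result. The rankings of peaks by width and signal and the ranks of promoter and distal signal below were likewise picked after the values were seen.

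The widest replicated peak lay over Lmx1b and spanned 18170 bp (chromosome 2, 33628808 to 33646977), followed by that over Hoxa10 (16067 bp). The next 8 by width, outside the naming rule, were nearest to Otulinl (14967 bp), Mrpl23 (12847 bp), Zmynd8 (12526 bp), Vasn (11624 bp), the tendon regulator Scx (11554 bp), 4930558K02Rik (11436 bp), Id3 (11247 bp) and Tbx15 (11134 bp). Of these 8, the peaks nearest to Zmynd8, Scx, Id3 and Tbx15 reached a TSS, and that nearest to Otulinl lay 94419 bp from it. The 5 peaks of highest signal were at Tnrc18 (77.0), Arrdc3 (65.0), Erbin (64.1), Kmt5b (62.8) and Sp3 (62.4), also outside the rule. By the median signal of marked promoters, Wnt genes (24.3, percentile 99.9 among marked genes of the same CpG class), hedgehog genes (23.5, percentile 99.9), FGF feedback genes (21.5, percentile 99.5) and limb patterning genes (16.8, percentile 100) stood high. So did HoxA (24.0, percentile 99.97), housekeeping (13.9, percentile 98.1), retinoic acid (16.3, percentile 97.9), chondrogenic (11.4, percentile 97.3) and HoxD genes (17.9, percentile 95.4). For the Wnt, hedgehog and FGF feedback lists the share of marked promoters had stayed below the 95th percentile with the replicated list. FGF feedback, with 13 of 13 marked, could rank no higher.

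Few ectoderm and apical ridge promoters were marked in the replicated list (8 of 23, percentile 0.065). The list of replicate 1 alone held 7 of 23 and that of replicate 2 alone 14 of 23 (percentile 21.8). The shortage was thus weaker in replicate 2, and why the replicates differed was not tested. The marked promoters had a median signal of 3.96, at percentile 0.65 of matched marked genes, and the distal peaks of the list 3.35, at percentile 1.71 of matched lists. Both values are consistent with ectoderm being a small share of the tissue. The promoter value is not specific to ectoderm, since the 3 marked neural promoters (4.04, percentile 2.66) and the marked muscle promoters (3.88, percentile 2.66) also ranked low. Distal peaks ranked lowest for ectoderm, then for retinoic acid (3.45, percentile 9.49) and Schwann and neural crest genes (3.48, percentile 14.9). They did not rank low for neural (3.98, percentile 98.4) or muscle genes (3.66, percentile 50.8). A low distal rank was thus not particular to ectoderm. Low activity of the ectoderm genes themselves stays open and was not tested.

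Some promoters of other cell types were marked (21 genes of the erythroid, macrophage, Schwann, neural, heart, liver and pluripotency lists). A neighbouring promoter could account for 3 of these peaks, Pmel with Cdk2, Mpz with Sdhc and Foxa3 with Sympk, and 18 had no other protein-coding TSS within reach of the peak. The share of 14.3% stood at percentile 44.9 of matched marked genes, which argues against neighbours as the cause for the list. Red blood cells in the tissue would bring their most active genes, yet 0 of 7 globin genes had a promoter peak in the pooled list, which argues against them as the whole source of the erythroid peaks. A red cell contribution stays open, since the domain of Hba-a2 held 1 replicated distal peak, those of Hba-a1 and Hba-x held 3 and 2 in replicate 2 only, and near-identical copies can lose reads in filtered alignments.

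CTCF sites were fewer in distal peaks than in flanks, with 712 and 2179 matches. Copies of repeats in the flanks could carry the site: without repeat-masked bases, 476 and 365 matches remained, a ratio of 1.32 in place of 0.399. The percentile among permuted forms was then 11.5, between the bounds set for and against this explanation. Repeats may account for the lower count of sites in peaks, while the low rank against permuted forms, whose median ratio was 1.64, cannot be told apart from a true shortage because the value fell between the bounds.

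How the replicated list was filled was also examined. Of 55458 pooled peaks found in a single replicate list, 24.2% were in the replicated list, so support in a single list was not enough for inclusion. Among the 76361 pooled peaks not found in both lists, a peak in the replicated list had a higher −log10 p than a peak outside it in a share of 0.811 of pairs. That value fell between bounds written beforehand, but a choice by −log10 p alone would give a share of 1. Peaks in the replicated list went down to a −log10 p of 2.03, while single-list peaks outside it had a median of 4.80.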
